A study of Mus musculus with 11 samples.

How the data were processed

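The samples were 11 libraries of ribosome-protected fragments, the short stretches of messenger RNA that a translating ribosome shields from nuclease, made from mouse cortex. Per the labels' protocols, the tissue was digested with micrococcal nuclease, monosomes were purified, ribosomes were captured with an antibody against the large-subunit protein P0, and the protected RNA was selected on a gel at 30 to 50 nt. The library inserts were given as 15 to 35 bp, a range that differs from the gel range, and no source used here explains the difference. Libraries came from a small RNA kit and were read as single ends of 69 bp on a MiSeq. No total RNA library was analysed here, so a change in footprints can come from the amount of a transcript or from how often it is translated, and the values below do not separate these.

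The deposited table holds whole-number footprint counts per Ensembl transcript, 1 column per library. Bowtie2, edgeR and the mouse build mm10 are named in the submitters' processing notes without versions or roles; the counting tool, the annotation release, the use of strand and the read filters are not given in the sources used here. The table has 9784 transcripts, each with a summed count of at least 101 over all libraries, so transcripts with fewer counts are not analysed here. Of these transcripts, 9736 matched a gene of the GENCODE vM21 annotation of mm10 by transcript identifier. The other 48 held 0.306% of all counts and stayed out of library totals and gene tests.

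Many transcripts of a gene carried identical counts: 2255 transcripts repeated an earlier one in all 11 libraries, 2219 of them within a gene. A read therefore appears to have been counted for every isoform it overlaps, and a sum over isoforms would count it repeatedly. Each of the 4338 genes was represented by its transcript with the highest summed count. Counts summed over these representatives ran from 35068 in ipsilateral replicate 4 to 571351 in contralateral replicate 6, a 16.3-fold range. These are shallow libraries, and at a library total of 35068 a count of 0 still allows 3 counts.

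The groups were those of the labels: sham surgery (replicates 1, 2 and 5), the hemisphere opposite the occlusion (1, 4, 5 and 6) and the occluded hemisphere (2, 4, 5 and 6). Replicates are animals from distinct days of surgery, and the replicate number names the day, so libraries of different groups with the same number share a day. Whether an ipsilateral and a contralateral library with the same number came from the same animal is not stated. The pairing by day comes from the submitters' design text. As a check, deviations from the group means were correlated between libraries across genes, which are not independent replicates. The 7 same-number pairs across groups gave r from -0.139 to 0.224 with a median of 0.131. The 33 other pairs ran from -0.255 to 0.259 with a median of -0.0300, which covers the whole range of the same-number pairs. The chi-square of counts per degree of freedom lay between 1.40 and 3.06 for the 15 pairs of libraries within groups and between 1.22 and 6.34 for the 40 pairs across groups, lowest for sham replicate 5 and contralateral replicate 5, so no column of counts is a copy of another.

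Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr over the 3 groups with a minimum count of 10, TMM factors, robust quasi-likelihood fits of all 11 libraries together without a block, and a quasi-likelihood F test for each of the 3 contrasts. The filter kept 3835 genes and removed 503. The common dispersion was 0.0291, a biological coefficient of variation of 0.171. P-values were adjusted by Benjamini-Hochberg within a comparison, at a threshold of 0.05. Levels are given as CPM (a count divided by the scaled library total, on the usual common scale) after TMM scaling, as mean ± SD.

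Gene lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Of the 32 lists, 23 had at least 5 tested members. Some were nearly complete, such as heat shock genes (20 of 23 tested) and neuron markers (23 of 24). Others were tested in part: 13 of 41 immediate early genes, 9 of 20 microglia and 6 of 16 striatal markers, 11 of 27 hypoxia genes and 10 of 39 miR-29 targets. A list result covers only the tested members. The other 9 were not tested: p53 targets and apoptosis, inflammatory cytokines, reactive astrocyte genes, endothelial and pericyte markers, meningeal and fibroblast markers, choroid plexus markers, hippocampal and thalamic markers, blood and leukocyte markers, and mitochondrially encoded genes. Each test was repeated with an inter-gene correlation estimated from the data. A list score of a library is the mean log2 CPM of the members minus the mean of the sham libraries.

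The lists, the tests, the named-gene rule and the alternatives were fixed before the data were examined, apart from 5 alternatives chosen after seeing the data. Genes named in the text are the 12 largest changes each way among genes that pass the threshold, whose groups do not overlap and whose mean CPM is at least 82.5, the 25th percentile of tested genes. To these come up to 4 members of each list with the smallest p in a comparison, and Slc1a1, Slc1a2, Slc1a3, Glul, Fos, Arc, Hspa1a, Hspa1b, Gfap and Bdnf throughout. Npas4 and Atf3 belong to that set and are not among the tested genes. Some genes that meet the rule are not reported here. Other genes are named only where a count of 5 or fewer, a gained or lost call or a single feature required it, and these were chosen after their values were seen.

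The alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, library totals alone, no filter, a filter of 30 counts in at least 3 libraries, only the compared groups, the replicate number as a block, counts thinned to the smallest library with and without that block, and each library left out in turn. The added ones were all transcripts, the mean over a gene's transcripts, the 9 libraries left without sham replicate 2 and ipsilateral replicate 4, the block with an estimated correlation, and the lists without Hspa1a and Hspa1b. The pipeline was tested on simulated negative binomial counts drawn from each gene's overall mean and dispersion and the library totals. Genes were drawn independently and without a day effect. Among 3835 simulated genes, the test recovered 38.8% of 67 genes changed 2-fold between ipsilateral and sham, 47.8% between ipsilateral and contralateral and 52.2% between contralateral and sham. For 66 genes changed 4-fold it recovered 84.8%, 92.4% and 97.0%, and for 67 genes changed 1.5-fold 2.99%, 8.96% and 16.4%. The same simulations held 5, 7 and 6 false calls, and with no gene changed the test called 1, 0 and 0 genes.

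Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Shared sequence was measured as the percent of a transcript's 28-nt words that also occur in a transcript of another gene.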

Results

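Ribosome footprints were measured in the cortex of C57BL6 mice aged 7 to 8 weeks after a stroke produced by blocking the right middle cerebral artery for 35 min with a filament, followed by 3 h of reperfusion. The occluded (ipsilateral) hemisphere was profiled in 4 libraries and the opposite (contralateral) hemisphere in 4. A further 3 libraries came from sham animals, whose arteries were exposed without a filament; the side their cortex came from is not stated, so a difference from sham can also hold a difference between sides. The series concerns the acute regulation of brain glutamate balance in stroke. Library totals, with each gene counted once, were 64460 to 256657 for sham, 137372 to 571351 for contralateral and 35068 to 137341 for ipsilateral cortex, with medians of 194996, 227277 and 103476. The ipsilateral libraries are thus the shallowest group. The labels of the 4 ipsilateral samples conflict, since their tissue entry names the contralateral hemisphere whereas their titles and descriptions name the ipsilateral side; the titles were followed.

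The comparison of ipsilateral with sham cortex asks what the ischaemic hemisphere translates 3 h after reperfusion. Footprints of the stress-induced 70 kDa chaperones rose steeply: Hspa1a rose by 5.28 ± 0.49 (log2, SE), to 3569 ± 1511 CPM (n = 4), and Hspa1b by 5.22 ± 0.48, from 103 ± 33.5 (n = 3) to 3544 ± 1453 CPM. Hspa5, the chaperone of the endoplasmic reticulum known as BiP, rose by 0.79 ± 0.16, from 1105 ± 130 to 1932 ± 253 CPM. Prg4, which encodes the secreted glycoprotein lubricin, rose by 2.62 ± 0.44, from 29.8 ± 13.4 to 206 ± 113 CPM. Every ipsilateral library lay above every sham library for each of these genes, and no gene fell. The edgeR test did not call Prg4 or Hspa5 against contralateral cortex, so their rise is not shown to be particular to the occluded hemisphere. Over all 11 libraries Prg4 averaged 118 CPM and Hspa5 1504 CPM. The plot of CPM per library shows the values behind these changes.

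**Figure D1:**
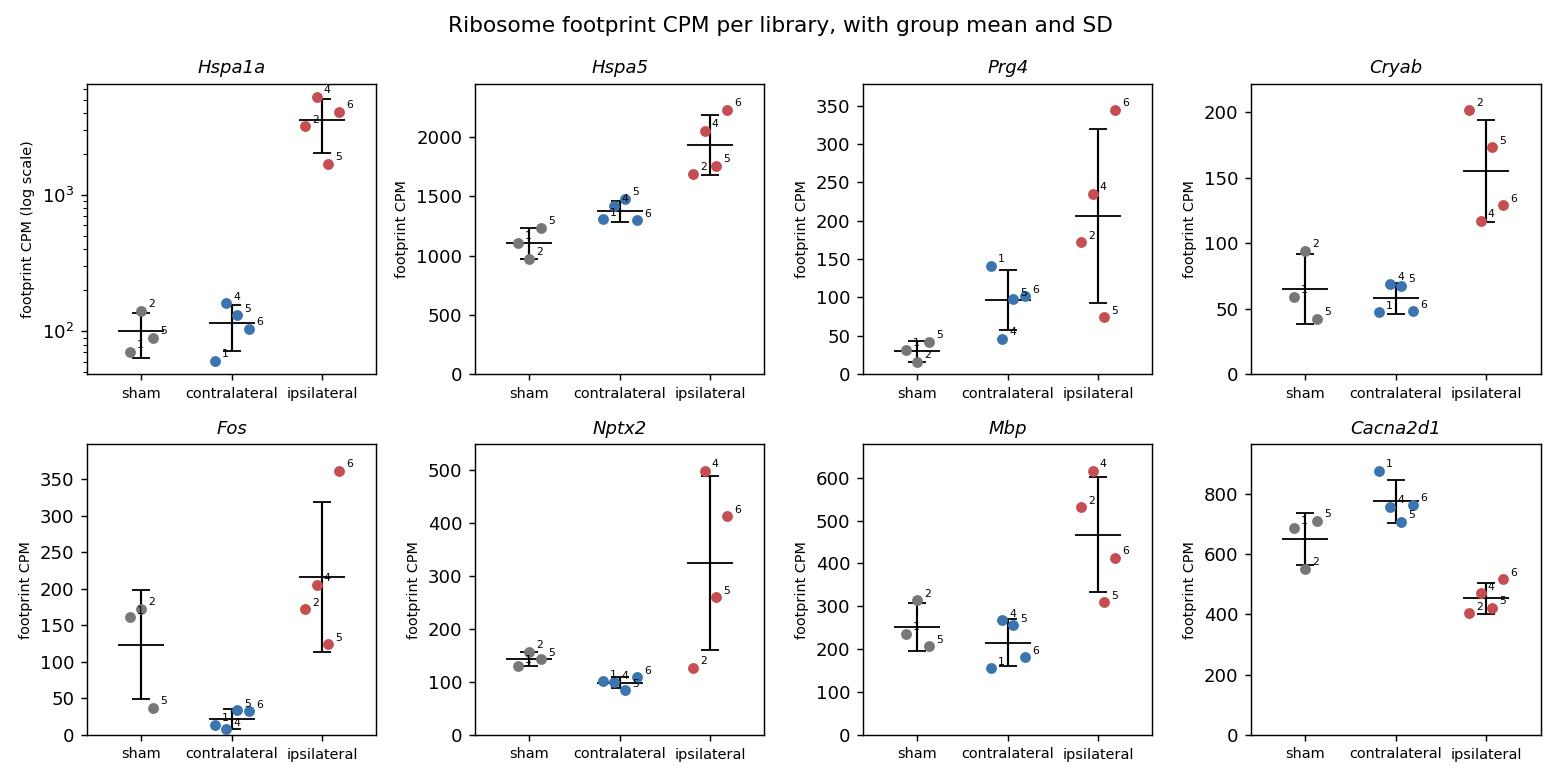
Ribosome footprint CPM (y axis, log scale for Hspa1a, linear from 0 for the others) of 8 genes in each library, grouped on the x axis as sham, contralateral and ipsilateral. Points are libraries with their replicate numbers, and black bars give the group mean and SD. Hspa1a averaged 3569 CPM ipsilaterally against 114 contralaterally, and Cacna2d1 averaged 452 against 775 CPM.

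Hspa1a lies on chromosome 17 from 34969190 to 34972156 and Hspa1b from 34956436 to 34959238, both on the minus strand of mm10. Of the 28-nt words of the Hspa1a transcript 64.6% occur in Hspa1b, and of those of Hspa1b 68.4% occur in Hspa1a, so how the counts divide between the copies is uncertain. Hspa1a also overlaps the antisense gene Gm20481 over 564 nt. Hspa5 lies on chromosome 2 from 34771970 to 34777547, and 0.165% of its words occur in another gene. Prg4 lies on chromosome 1 from 150449412 to 150466165. It overlaps the oppositely oriented Tpr by 67 nt of its 3821 nt transcript, and Tpr measured 145 ± 64.8 CPM in sham and 93.1 ± 21.2 CPM in ipsilateral cortex.

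Groups of stress genes moved with these. The heat shock and co-chaperone list was higher in ipsilateral than in sham cortex (18 of 20 members above 0, mean log2 change 0.75, median 0.31, camera adjusted p = 1.7e-06). The mean rests largely on the near copies Hspa1a and Hspa1b, and without them it was 0.28 (adjusted p = 0.0023). With all 20 members its adjusted p was 0.0126 with an estimated correlation, and 0.101 when the replicate number was a block as well. Within it 2 members rose and 18 did not pass, or 5 rose when adjusted over the list alone; Cryab, a small heat shock protein, measured 155 ± 39.2 against 65.2 ± 26.5 CPM (log2 change 1.49 ± 0.34, edgeR adjusted p = 0.0578). The list of the integrated stress and unfolded protein responses was higher (18 of 20 members above 0, mean 0.32, adjusted p = 0.00017), with adjusted p = 0.150 with an estimated correlation. Hspa5 was its only member to rise, over all genes and adjusted over the list alone. Herpud1, which serves degradation of misfolded proteins, changed by 0.59 ± 0.27 (adjusted p = 0.591), the transcription factor Atf4 by 1.04 ± 0.49 (0.628) and the chaperone Hsp90b1 by 0.41 ± 0.17 (0.514). The cholesterol synthesis list was higher (12 of 13 members above 0, mean 0.43, adjusted p = 0.00017), with adjusted p = 0.152 with an estimated correlation. None of its members passed, and none did when adjusted over the list alone; Dhcr7, the last enzyme of the pathway, measured 96.5 ± 17.9 against 44.6 ± 16.2 CPM (log2 change 1.22 ± 0.40), and Insig1 changed by 1.11 ± 0.50.

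Some lists of glial markers also differed. Oligodendrocyte markers were higher in ipsilateral than in sham cortex in 12 of 12 members (mean 0.73, camera adjusted p = 4.7e-08), with adjusted p = 0.177 with an estimated correlation. No member passed over all genes and 9 rose when adjusted over the list alone. Examples are the myelin gene Cldn11 (283 ± 111 against 130 ± 24.5 CPM, log2 change 1.15 ± 0.29), Ptgds (1601 ± 554 against 905 ± 22.4 CPM, 0.83 ± 0.19) and Trf (1.02 ± 0.26). Trf shares 2108 nt with Gm20425, so its counts are uncertain. Microglia markers were higher in 8 of 9 members (mean 0.69, adjusted p = 3.1e-06, 0.0232 with an estimated correlation and 0.223 when the replicate number was a block as well). None passed over all genes, and 6 rose when adjusted over the list alone, among them the receptor gene Cx3cr1 (122 ± 23.8 against 39.5 ± 23.9 CPM) and the complement gene C1qc (log2 change 1.08 ± 0.33). Astrocyte markers did not pass (mean 0.11, adjusted p = 0.102), and Gfap, the astrocyte filament, changed by 0.78 ± 0.35 (edgeR adjusted p = 0.571). The list of replication-dependent histones was higher (6 of 7 members above 0, mean 0.43, adjusted p = 0.00959, and 0.419 with an estimated correlation), with 0 members passing and 3 when adjusted over the list alone. These were Hist1h1d (1.63 ± 0.38), Hist1h1c (1.16 ± 0.30) and Hist1h1e, whose transcript shares 496 nt with Hist1h2be and is uncertain.

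Markers of striatal neurons were lower (1 of 6 members above 0, mean -0.72, camera adjusted p = 0.00946, and 0.410 with an estimated correlation). No member passed and 1 fell when adjusted over the list alone; Ppp1r1b, encoding DARPP-32, measured 115 ± 66.5 against 257 ± 49.7 CPM (log2 change -0.87 ± 0.29). This list did not pass with the replicate number as a block (adjusted p = 0.127) or without sham replicate 1 (0.0516), ipsilateral replicate 4 (0.0899) or ipsilateral replicate 5 (0.0602). The histone list did not pass without sham replicate 1 (0.0530), sham replicate 5 (0.107), ipsilateral replicate 2 (0.0599) or ipsilateral replicate 6 (0.187). With the block, the lists of ribosomal proteins (0.0456) and translation factors (0.0195) passed, which without it had 0.0503 and 0.102. With an estimated correlation both had 0.419 without the block, and with the block 0 lists passed.

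Genes of glutamate transport and metabolism did not pass as a list (12 of 19 members above 0, mean 0.03, camera adjusted p = 0.474), and 0 members passed over all genes or adjusted over the list alone. The astrocytic transporters Slc1a2 and Slc1a3 changed by 0.08 ± 0.16 and 0.25 ± 0.17, the neuronal transporter Slc1a1 by 0.54 ± 0.25 and glutamine synthetase, Glul, by -0.04 ± 0.14. Slc1a2 measured 3814 ± 468 against 3604 ± 429 CPM. Gad2, which makes the inhibitory transmitter GABA from glutamate, changed by 0.83 ± 0.34 (edgeR adjusted p = 0.530). Immediate early genes did not pass either (7 of 13 members above 0, adjusted p = 0.686): Fos changed by 0.94 ± 0.44, Jun by 1.36 ± 0.47, Arc by -0.24 ± 0.55, and the neurotrophin gene Bdnf by 0.36 ± 0.43. Only 13 of the 41 fixed immediate early genes were tested, so the rest of that list was not assessed. Single genes of other lists also missed the threshold, among them the growth-arrest gene Cdkn1a (1.42 ± 0.37, adjusted p = 0.0978), Apod (1.34 ± 0.32, 0.0900), Sparc (1.14 ± 0.30, 0.178) and the hypoxia gene Ndrg1 (1.11 ± 0.42, 0.416).

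In sum, the edgeR quasi-likelihood test called 4 genes higher and 0 lower of 3835, with adjusted p of 0.00257 for Hspa1a, Hspa1b and Prg4 and 0.00932 for Hspa5. At an unadjusted p under 0.05 stood 297 genes, 164 higher and 133 lower, and the groups did not overlap for 276 genes, 7.20% where chance gives 5.71%. DESeq2 called 10 genes and limma-voom 5; Prg4 had an adjusted p of 0.180 in limma-voom, and DESeq2 gave it no adjusted p. The count was 0 without sham replicate 1, where Hspa1a kept a log2 change of 5.05 at an adjusted p of 0.0504, 2 without sham replicate 5 and 22 without ipsilateral replicate 5; with the replicate number as a block Hspa5 had an adjusted p of 0.0940. Hspa5 also missed the threshold without sham replicate 2 (0.0655) or ipsilateral replicate 6 (0.0572), and Prg4 and Hspa5 did without sham replicate 1 (0.132 for both). Without the 2 shallowest libraries Prg4 (0.0708) and Hspa5 (0.122) missed it as well.

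**Figure D2:**
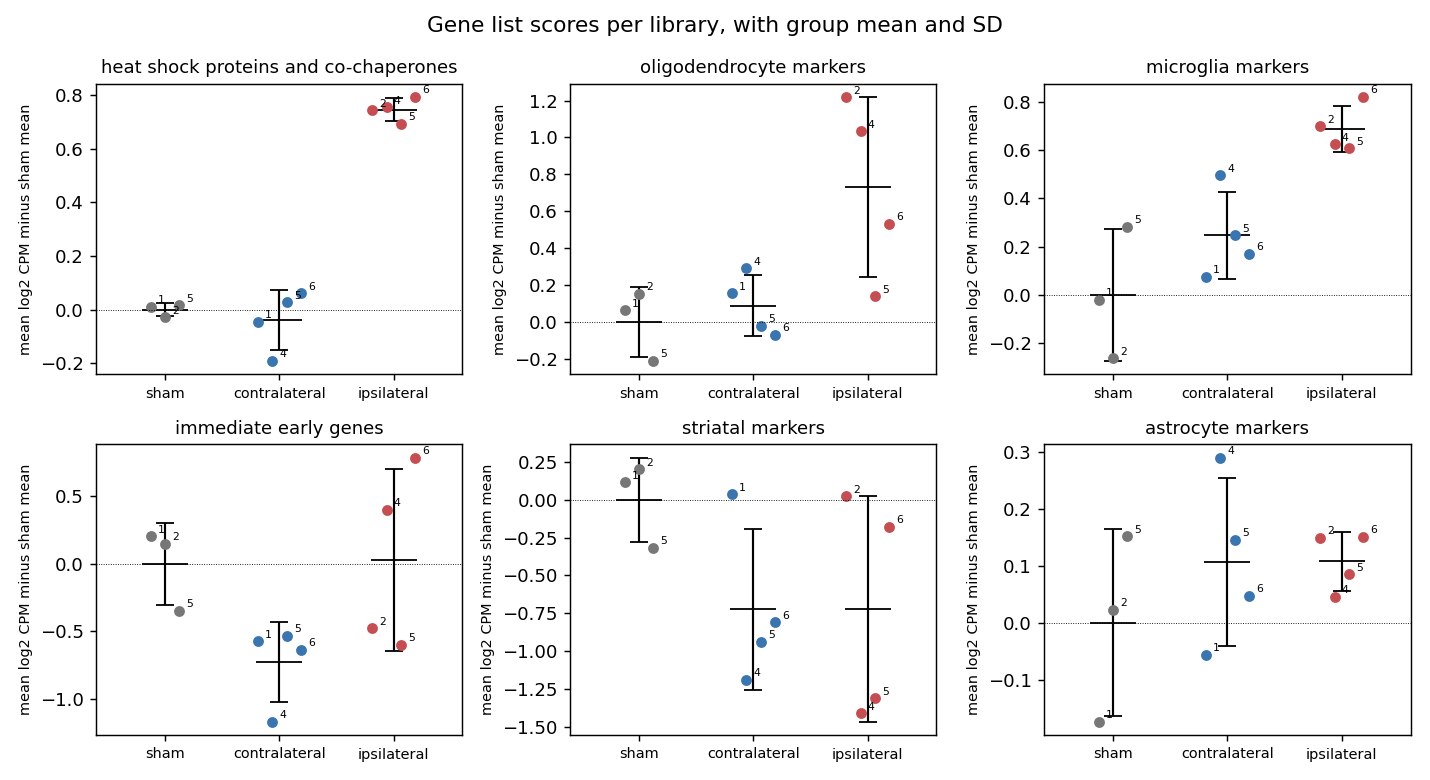
Scores of 6 gene lists (y axis, mean log2 CPM of the members minus the mean of the sham libraries) in each library, grouped on the x axis as sham, contralateral and ipsilateral. Points are libraries with their replicate numbers, and black bars give the group mean and SD. Heat shock scores of the ipsilateral libraries lay between 0.69 and 0.79, whereas their oligodendrocyte scores ranged from 0.14 to 1.22.

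The comparison of ipsilateral with contralateral cortex contrasts the occluded hemisphere with the unoccluded hemisphere of animals with an occlusion. Here 13 genes rose and 1 fell. The chaperones again led, Hspa1b by 4.99 ± 0.39 and Hspa1a by 4.95 ± 0.40, from 109 ± 42.0 and 114 ± 42.4 CPM (n = 4 in both groups), with Cryab by 1.53 ± 0.29, from 57.8 ± 11.9 to 155 ± 39.2 CPM, and the co-chaperone Dnajb1 by 1.24 ± 0.30. Fos, the immediate early transcription factor, rose by 3.03 ± 0.48, from 21.7 ± 13.1 to 216 ± 103 CPM, and Nptx2, an activity-regulated synaptic pentraxin, by 1.56 ± 0.28, from 98.2 ± 10.2 to 325 ± 165 CPM. The myelin genes Mbp (1.09 ± 0.22), Cldn11 (1.07 ± 0.25) and Mag (1.06 ± 0.24) rose, as did the globin genes Hba-a1 (1.13 ± 0.23) and Hba-a2 (1.14 ± 0.26). Cacna2d1, a subunit of voltage-gated calcium channels, fell by 0.78 ± 0.17 (log2, SE), from 775 ± 71.5 to 452 ± 50.9 CPM.

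Fos lies on chromosome 12 from 85473890 to 85477273, Nptx2 on chromosome 5 from 144545902 to 144557478, Cacna2d1 on chromosome 5 from 15934691 to 16374511 and Mbp on chromosome 18 from 82475146 to 82585637. At most 0.192% of the 28-nt words of these transcripts occur in another gene. Hba-a1 shares 71.9% of its words with Hba-a2 and Hba-a2 91.7% with Hba-a1, so these near copies count as a single uncertain signal. Hba-a1 measured 329 ± 70.2 CPM ipsilaterally, 142 ± 28.4 contralaterally and 263 ± 61.6 in sham cortex.

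As a group, heat shock proteins and co-chaperones were higher (18 of 20 members above 0, mean log2 change 0.78, median 0.27, camera adjusted p = 4.0e-08, 0.00511 with an estimated correlation and 0.0748 when the replicate number was a block as well); 4 members rose, and 4 when adjusted over the list alone. Without the near copies Hspa1a and Hspa1b the mean was 0.33 (adjusted p = 0.00015). Immediate early genes were higher (11 of 13 members above 0, mean 0.76, adjusted p = 1.0e-06), with adjusted p = 0.220 with an estimated correlation. Its score was 0.40 and 0.78 in ipsilateral replicates 4 and 6 but -0.48 and -0.60 in replicates 2 and 5, which lie within the contralateral range of -1.17 to -0.54 or just above it. Over all tested genes single libraries stood apart, ipsilateral replicates 4 and 6 among them. On the first principal component of log2 CPM (30.3% of the variance) ipsilateral replicate 4 lay at 49.3 and the other libraries at -8.78 to 3.82. On the third (12.4%) ipsilateral replicate 6 lay lowest at -24.9. Sham replicate 2 lay lowest on the second (18.3%), at -32.7, followed by ipsilateral replicate 6 at -14.8. Ipsilateral replicate 5 stood apart on the fourth, at 25.5 against -8.49 to 6.46 elsewhere. Ipsilateral replicate 4 and sham replicate 2 are the 2 shallowest libraries (35068 and 64460 counts), so their positions cannot be told apart from depth. Without ipsilateral replicate 4 the mean change of the immediate early gene list was 0.64 (adjusted p = 0.00015), and without replicate 6 it was 0.51 (0.0012). Fos rose, and 4 members did when adjusted over the list alone; Per1 (1.17 ± 0.34), Jun (1.15 ± 0.40), Arc (1.27 ± 0.56) and Ier5 (0.80 ± 0.28) had adjusted p over all genes of 0.174, 0.395, 0.648 and 0.312. Activity-dependent secreted factors were higher (10 of 11 members above 0, mean 0.55, adjusted p = 9.3e-05, and 0.0778 with an estimated correlation). Nptx2 rose and 3 members did when adjusted over the list alone, the neuropeptide precursor gene Vgf measuring 1117 ± 271 against 723 ± 132 CPM and the signalling regulator Rgs2 108 ± 29.6 against 39.8 ± 27.2 CPM. Bdnf changed by 0.39 ± 0.38. Against sham, the ipsilateral mean change was 0.03 for immediate early genes and 0.14 for activity-dependent factors (camera adjusted p = 0.686 and 0.222). The contralateral means against sham were -0.73 and -0.41. Most of the difference between hemispheres in these lists thus lay in the lower contralateral values.

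Oligodendrocyte markers were higher in 11 of 12 members (mean 0.64, camera adjusted p = 5.4e-08), with adjusted p = 0.220 with an estimated correlation; 4 rose over all genes and 7 when adjusted over the list alone. The score of this list was 1.22, 1.03, 0.14 and 0.53 in ipsilateral replicates 2, 4, 5 and 6. Microglia markers were higher in 9 of 9 members (mean 0.44, adjusted p = 0.00016, and 0.0730 with an estimated correlation); 0 passed over all genes and 2 when adjusted over the list alone, C1qb changing by 1.06 ± 0.28 and C1qc measuring 148 ± 26.9 against 81.5 ± 16.0 CPM. Cytosolic ribosomal proteins were higher (37 of 48 members above 0, mean 0.17, adjusted p = 0.00099, and 0.261 with an estimated correlation) with 0 members passing over all genes or adjusted over the list alone. Rps3, Rpl37 and Rpl3 changed by 0.76, 0.87 and 0.65, and without ipsilateral replicate 2 the list had an adjusted p of 0.0845.

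**Figure D3:**
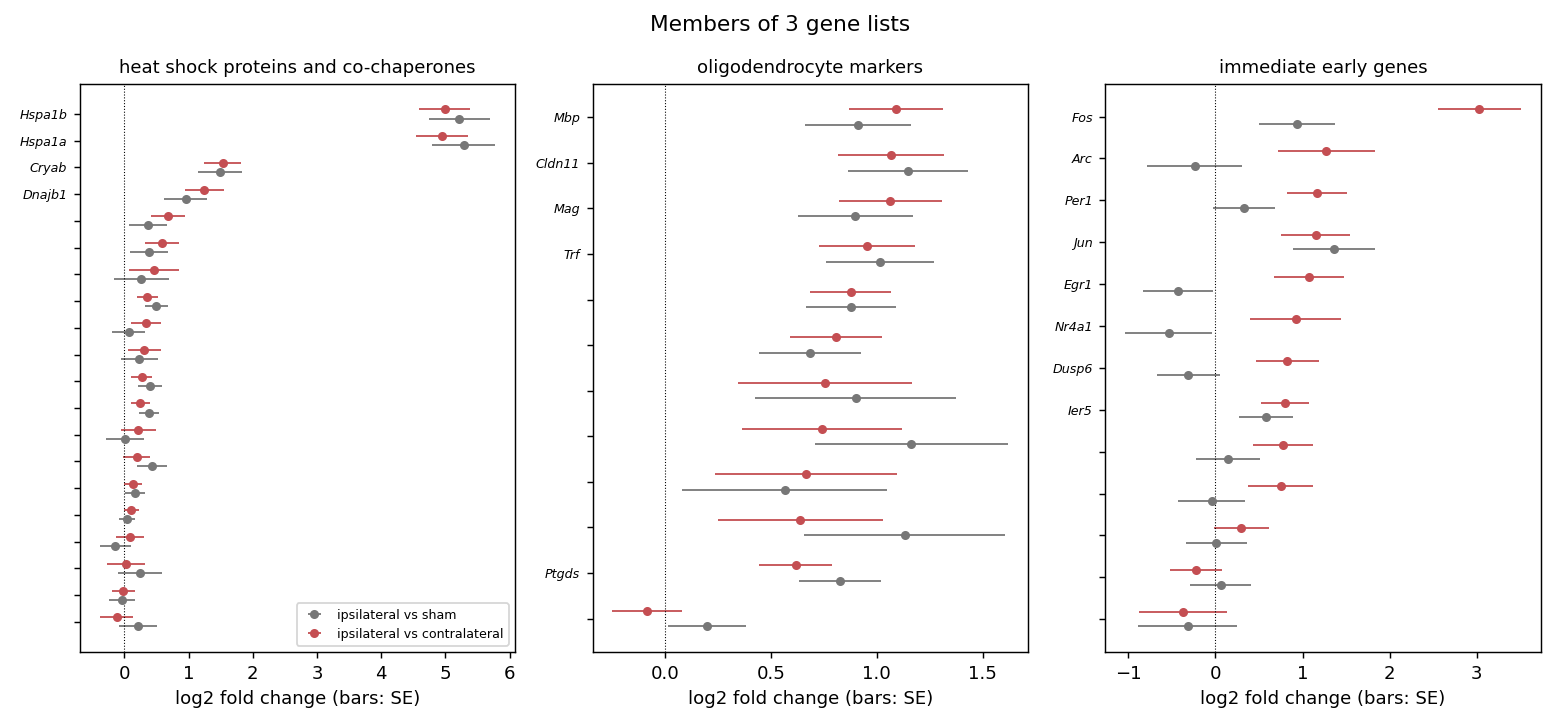
Log2 fold change (x axis) of each tested member (y axis) of the heat shock, oligodendrocyte and immediate early gene lists, for ipsilateral against sham (grey) and ipsilateral against contralateral (red), with bars for the SE. Members named in the text are labelled. Of the 20 heat shock members 18 lay above 0 in each comparison, with Hspa1a and Hspa1b far beyond the rest. Of the 13 immediate early genes 11 lay above 0 against contralateral and 7 against sham cortex.

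Glutamate transport and metabolism did not pass (10 of 19 members above 0, camera adjusted p = 0.800), with 0 members over all genes and 1 when adjusted over the list alone. Slc1a2 changed by -0.35 ± 0.15 (edgeR adjusted p = 0.530), Slc1a1 by 0.07 ± 0.22, Glul by -0.11 ± 0.12, Gad1 by 0.53 ± 0.16 (0.202) and Gad2 by 0.87 ± 0.30 (0.390). Slc1a3 measured 1268 ± 313 against 1252 ± 79.9 CPM. Gfap changed by 0.55 ± 0.30 (0.680) and Cdkn1a by 1.24 ± 0.31 (0.0706). Beside the alpha globins, Hbb-bs and Hbb-bt each changed by 0.79 ± 0.24 (0.199 and 0.202). Ccn3, a secreted matrix protein gene, measured 327 ± 89.3 against 569 ± 50.3 CPM (0.0867).

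The edgeR test gave adjusted p of 0.00121 for Hspa1a and Hspa1b, 0.00247 for Nptx2, 0.00470 for Cryab, 0.00609 for Fos, 0.00987 for Mbp and Hba-a1, 0.0147 for Cacna2d1, 0.0257 for Hba-a2, 0.0350 for Mag, 0.0372 for Cldn11 and 0.0471 for Dnajb1. At an unadjusted p under 0.05 stood 292 genes, 186 higher and 106 lower, and the groups did not overlap for 169 genes, 4.41% where chance gives 2.86%. With the replicate number as a block 11 genes passed, 8 of them among the 14; Cryab (0.124), Mbp (0.0813), Mag (0.0508), Cldn11 (0.139), Dnajb1 (0.139) and Cacna2d1 (0.124) did not. The count was 4 without contralateral replicate 6, 6 without contralateral replicate 1, 6 without ipsilateral replicate 2, 9 without ipsilateral replicate 4, 26 without ipsilateral replicate 5 and 8 without the 2 shallowest libraries; Hspa1a and Hspa1b passed in all of these. Without ipsilateral replicate 6, Dnajb1 changed by 0.62 with an adjusted p of 0.925, and Nptx2 had 0.0504. Fos missed the threshold without the 2 shallowest libraries (0.121) and in limma-voom (0.102). Dnajb1 missed it in most alternatives, among them median-ratio factors (0.0513), library totals alone (0.0556), DESeq2 (0.125) and limma-voom (0.115).

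The comparison of contralateral with sham cortex asks whether footprints outside the occluded territory differ between animals with the filament occlusion and sham-operated animals. The edgeR test called 0 genes, while DESeq2 called 2. Immediate early genes lay at lower levels contralaterally: Fos measured 21.7 ± 13.1 CPM (n = 4) against 124 ± 75.2 CPM (n = 3), a log2 change of -2.09 ± 0.52, and Egr1 158 ± 18.9 against 462 ± 230 CPM (-1.50 ± 0.39). As a group, these genes were lower (3 of 13 members above 0, mean -0.73, camera adjusted p = 3.7e-06), with adjusted p = 0.314 with an estimated correlation. Of the list, 0 members passed over all genes and 6 fell when adjusted over the list alone. Nr4a1, Dusp6 and Arc changed by -1.46 ± 0.45, -1.14 ± 0.33 and -1.51 ± 0.53.

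Activity-dependent secreted factors were lower (3 of 11 members above 0, mean -0.41, camera adjusted p = 0.00849, and 0.314 with an estimated correlation), with 0 passing and 1 falling when adjusted over the list alone. Vgf measured 723 ± 132 against 1122 ± 275 CPM, the prostaglandin synthase gene Ptgs2 49.5 ± 10.6 against 106 ± 30.7 CPM and Rgs2 39.8 ± 27.2 against 94.1 ± 18.3 CPM, while Bdnf changed by -0.02 ± 0.37. Striatal markers were lower (1 of 6 members above 0, mean -0.72, adjusted p = 0.00246, and 0.314 with an estimated correlation); 0 passed over all genes and 3 fell when adjusted over the list alone. With the replicate number as a block the mean was -0.40 (adjusted p = 0.0263). Ppp1r1b measured 112 ± 22.1 against 257 ± 49.7 CPM (-1.11 ± 0.25), and Adcy5 and Penk changed by -0.99 ± 0.40 and -0.98 ± 0.63. The striatal score was 0.04 in contralateral replicate 1 and -1.19, -0.94 and -0.81 in replicates 4, 5 and 6.

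Lists that were higher contralaterally had smaller mean changes. Glutamate receptors and postsynaptic scaffold genes had 18 of 24 members above 0 (mean 0.20, camera adjusted p = 0.00849, and 0.314 with an estimated correlation), with Shank1, Gria1 and Gria2 at 0.87, 0.36 and 0.33. The integrated stress and unfolded protein response list had 15 of 20 above 0 (mean 0.19, adjusted p = 0.00849, and 0.314 with an estimated correlation), with the chaperones Hsp90b1 and Canx at 0.53 and 0.44. For both lists 0 members passed over all genes or adjusted over the list alone. Cholesterol synthesis had 11 of 13 above 0 (mean 0.27, adjusted p = 0.00849, and 0.314 with an estimated correlation), Dhcr7 (1.21 ± 0.35) being the only member to rise when adjusted over the list alone, beside Insig1 at 0.62. Replication-dependent histones had 7 of 7 above 0 (mean 0.31, adjusted p = 0.0438, and 0.554 with an estimated correlation), with 1 rising when adjusted over the list alone and Hist1h1c at 0.80 ± 0.28. With the replicate number as a block, adjusted p was 0.456 for glutamate receptors and for cholesterol synthesis, 0.306 for the stress response list and 0.0560 for histones, so 3 lists passed in place of 7.

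Glutamate transport and metabolism did not pass (9 of 19 members above 0, mean 0.03, camera adjusted p = 0.777), with 0 members over all genes or adjusted over the list alone. Slc1a2 changed by 0.43 ± 0.16 (edgeR adjusted p = 0.771), Slc1a1 by 0.47 ± 0.23, Slc1a3 by 0.25 ± 0.17 and Glul by 0.07 ± 0.13. Hspa1a and Hspa1b changed by 0.34 ± 0.54 and 0.23 ± 0.53 and Gfap by 0.23 ± 0.32. The globin genes Hba-a1 and Hba-a2 measured 142 ± 28.4 and 133 ± 39.7 CPM against 263 ± 61.6 and 255 ± 105 CPM in sham cortex (adjusted p = 0.636 for both).

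The edgeR test called 0 of 3835 genes, with a smallest adjusted p of 0.244, for Ppp1r1b; 217 genes had an unadjusted p under 0.05, 97 higher and 120 lower, DESeq2 called 2 (Egr1 and Fos, both lower) and limma-voom 0. The groups did not overlap for 295 genes, 7.69% where chance gives 5.71%. Without sham replicate 5 the count was 3 (Egr1, Fos and Nr4a1) and without ipsilateral replicate 6, which enters only through the shared spread, 1 (Fos). Without contralateral replicate 4 only 2 lists passed, immediate early genes and striatal markers. The calls for activity-dependent factors (adjusted p = 0.123 without sham replicate 1), the stress response list (0.0656 without sham replicate 2) and histones (0.228, 0.449, 0.0923, 0.0949 and 0.0522 without sham 1, sham 5, contralateral 5, contralateral 6 and ipsilateral 4) also rested on further libraries.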

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

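The counts over other splits of the libraries were weighed after the results had been seen. No signal was found among the 48 transcripts without a gene: with all transcripts tested, 0 of them passed in any comparison.

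In 172 groups of 4 libraries (library totals, the CPM of named genes and the scores of tested lists), 7 held a library far from the other 3, where chance gives about 1 in 20, or 8.6. The gap to the nearest library, as a share of the group's range, was 0.962 for Egr1, low in contralateral replicate 4, and 0.836 for the immediate early gene score, low in the same library. It was 0.960 for Ppp1r1b, high in contralateral replicate 5, 0.847 for Per1, high in contralateral replicate 1, and 0.858 for Ptgs2, low in contralateral replicate 1. It was 0.874 for Insig1, high in ipsilateral replicate 6, and 0.865 for Sparc, high in ipsilateral replicate 2, at 1278 CPM against 445 to 557 CPM in the other ipsilateral libraries.

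The change from sham differed between the hemispheres for the genes called in the ipsilateral against contralateral contrast, which is the edgeR test of that difference. The difference was 4.99 for Hspa1b, 4.95 for Hspa1a, 1.56 for Nptx2, 1.53 for Cryab, 3.03 for Fos, 1.09 for Mbp, 1.13 for Hba-a1, 1.14 for Hba-a2, 1.06 for Mag, 1.07 for Cldn11, 1.24 for Dnajb1 and -0.78 for Cacna2d1 (log2). For the chaperones it lay on the ipsilateral side, where Hspa1a changed by 5.28 against 0.34 contralaterally. For Fos the hemispheres lay on opposite sides of sham, at 0.94 ipsilaterally and -2.09 contralaterally, as did Nptx2 at 1.07 and -0.49. The larger part of the Fos difference thus lay in the lower contralateral value. The edgeR test called neither gene against sham in either hemisphere, so opposite responses are not shown. Hba-a1 stood at 0.24 ipsilaterally and -0.88 contralaterally, so most of its difference lay in the lower contralateral value.

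Other divisions of the same libraries into groups of the same sizes were tested for each comparison, 35 of them including the real one. For ipsilateral against contralateral genes, 1 of 35 gave as many as the real division, itself, with 14 genes against at most 8 in another. That share is under 0.05, but libraries share days of surgery, so the 35 are not fully exchangeable. Among the divisions that part as many same-day pairs, the 7 others gave at most 0, and these are too few for a share under 0.05. For the number of ipsilateral against sham genes chance cannot be excluded: 4 of 35 gave at least 4 genes, and the highest other gave 21. That division joined ipsilateral replicate 5 to the sham libraries, still setting 3 of the 4 ipsilateral libraries against them, and parts 1 same-day pair, which points to a structure of the samples that was not tested further; the 11 other divisions parting 2 pairs as the real one does gave at most 3. For contralateral against sham genes the real count of 0 is reached by all 35 by construction, with 1 in the highest other, so the divisions say nothing about it.

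A number of genes does not weigh the size of a change. For Hspa1a and Hspa1b, near copies named before the data were examined, the size of the change argues against chance. They rose by 5.28 ± 0.49 and 5.22 ± 0.48 against sham (log2, SE), and by 4.55 and 4.52 with the replicate number as a block. Against contralateral cortex Hspa1a changed by 4.71 to 5.18 over its alternatives and passed in each. The difference of mean log2 (CPM + 1) from sham, 5.08 and 5.02, was reached in 1 of 35 divisions, the real one, with 4.37 in the highest other. The divisions alone cannot exclude chance, since 1 of 35 is the smallest share possible and they are not fully exchangeable. Against sham, Slc1a1 ipsilaterally (0.73, highest other 0.70) and Fos contralaterally (-2.40, highest other 2.32) also reached 1 of 35 without being called by edgeR. The edgeR calls of Hspa1a and Hspa1b against sham were lost without sham replicate 1 or 5 (adjusted p = 0.0504 and 0.0505). Hspa1a kept changes of 5.05 and 5.28 there. For Prg4 and Hspa5, whose smaller changes also lose their calls in some alternatives, chance stays open.

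For the number of lists passing, chance cannot be excluded in any comparison. At least the real 7 lists passed in 2 of 35 divisions of ipsilateral and sham libraries, with 10 in the highest other, the one with ipsilateral replicate 5 among the sham libraries; the 11 divisions parting as many same-day pairs as the real one gave at most 6. The real 6 were reached in 6 of 35 for ipsilateral and contralateral libraries, with 11 in the highest other, which is also the highest of the 7 parting as many pairs. The real 7 were reached in 5 of 35 for contralateral and sham libraries, with 10 in the highest other and at most 7 in the 11 parting as many pairs.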

How the results depend on the processing

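All transcripts, means over transcripts, leaving out the 2 shallowest libraries, the block with an estimated correlation and the lists without Hspa1a and Hspa1b were alternatives chosen after seeing the data. The cause of a change was not tested unless stated.

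Of the alternative values of called genes, 268 kept direction and call and 86 kept direction only; of genes not called, 1682 kept direction and call, 34 passed and 26 changed sign. For passing lists 311 kept both and 65 direction only; for the glutamate list 55 kept both and 2 changed sign. DESeq2 gave no adjusted p for 20 of the 98 named values, Prg4 among them, and these are left out. Genes with too few counts to be tested under the stricter filter or the thinned counts, called genes among them, have no value there. They are left out of these numbers too. Against contralateral cortex, Hspa1a and Hspa1b kept their call in every alternative; against sham they kept direction and lost the call in the fit of the compared groups alone (Hspa1a, 0.0526) or without sham replicate 1 or 5.

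Gene counts stayed within 1.5 times the stated ones except as follows. With DESeq2, ipsilateral against sham gave 10 genes (3 of the 4) and contralateral against sham 2. With counts thinned to the smallest library, which leaves 1034 testable genes, ipsilateral against contralateral gave 4 (2 of the 14). Mbp, Mag, Cldn11, Hba-a1, Hba-a2 and Cacna2d1 were testable there and missed the threshold (edgeR adjusted p from 0.125 to 0.772). Thinned with the replicate block, ipsilateral against sham gave 7 (2 of the 4) and contralateral against sham 2. Ipsilateral against contralateral then gave 11, a count within 1.5 times, but with only 4 of the 14 among them. Without the 2 shallowest libraries, ipsilateral against contralateral gave 8. Leaving out 1 library at a time gave 0 to 22 genes for ipsilateral against sham, 4 to 26 for ipsilateral against contralateral and 0 to 3 for contralateral against sham.

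With an estimated inter-gene correlation, 2 lists passed for ipsilateral against sham, 1 for ipsilateral against contralateral and 0 for contralateral against sham; with the replicate block as well, 0 passed in any comparison. The replicate block alone left 3 lists for contralateral against sham. Leaving out 1 library gave 5 to 9, 5 to 10 and 2 to 10 lists in the 3 comparisons. Beyond the calls named beside the results, the replicate block changed no other call of a named gene or passing list.

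Sign changes, all of values not past the threshold, in log2: with the replicate block Slc1a2 (-0.11) and Arc (0.12) against sham ipsilaterally, and Glul (-0.0210), Hspa1a (-0.16) and Hspa1b (-0.25) contralaterally. With thinned counts, Slc1a2 ipsilaterally (-0.00445), Glul contralaterally (-0.0197) and Slc1a3 ipsilateral against contralateral (0.0391); with thinning and the replicate block, Slc1a2 (-0.18), Glul (-0.0721) and Slc1a3 (0.0454). Slc1a3 was 0.0146 with the stricter filter and 0.0104 as a mean over transcripts, and Bdnf contralaterally 0.0102 with DESeq2. Leaving out 1 library, ipsilateral against sham gave -0.10 to 0.0769 for Glul, -0.77 to 0.63 for Arc and -0.26 to 0.73 for Bdnf; ipsilateral against contralateral -0.24 to 0.76 for Bdnf, -0.0164 to 0.11 for Slc1a1 and -0.11 to 0.14 for Slc1a3; contralateral against sham -0.0868 to 0.13 for Bdnf and -0.00195 to 0.0606 for the mean of the glutamate list.

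The smallest library holds 35068 counts, and thinning the others to it left 1034 testable genes in place of 3835. The simulations used the library totals and gene dispersions of these data, but drew genes independently and without a day effect. Their figures therefore need not hold for the real libraries. Simulated recovery of 2-fold changes was 38.8% for ipsilateral against sham, 47.8% for ipsilateral against contralateral and 52.2% for contralateral against sham. There were 5, 7 and 6 false calls and, with no gene changed, 1, 0 and 0 calls.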

Other observations

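Several groups of neuronal, metabolic and signalling genes did not pass as lists with the filter, scaling and preset correlation described for the tests. Neuron markers had camera adjusted p of 0.921 for ipsilateral against sham, 0.586 for ipsilateral against contralateral and 0.427 for contralateral against sham, and presynaptic release genes 0.222, 0.586 and 0.579. Nuclear-encoded oxidative phosphorylation genes (68 members) had 0.155, 0.591 and 0.265, and voltage-gated and inward-rectifier channels, to which Cacna2d1 belongs, 0.833, 0.957 and 0.914. Hypoxia response genes had 0.325, 0.125 and 0.599, the circadian clock 0.189, 0.957 and 0.138, glucocorticoid-induced genes 0.295, 0.125 and 0.599, and targets of the microRNA miR-29 taken from general knowledge 0.189, 0.840 and 0.265. Astrocyte markers had 0.102, 0.927 and 0.0738, oligodendrocyte precursor markers 0.189, 0.163 and 0.959, and translation factors 0.102, 0.591 and 0.213.

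The remaining results of lists that passed in another comparison were 0.222 and 0.315 for glutamate receptors ipsilaterally against sham and against contralateral cortex, 0.222 for activity-dependent factors ipsilaterally against sham, and 0.427 for ribosomal proteins contralaterally against sham. Contralaterally against sham they were 0.911 for heat shock genes, 0.0926 for microglia and 0.466 for oligodendrocyte markers. For ipsilateral against contralateral they were 0.151 for the stress response list, 0.957 for striatal markers, 0.125 for cholesterol synthesis and 0.315 for histones.

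A p that misses the threshold does not show that a group stayed level, and some of these lists passed in other settings, all at the preset correlation. With a filter of 30 counts in at least 3 libraries, miR-29 targets (mean 0.34, adjusted p = 0.0225, against 0.16 and 0.265) and astrocyte markers (0.0412) passed, higher, for contralateral against sham. Without the 2 shallowest libraries astrocyte markers (0.0271) did so too, and glutamate receptors were lower for ipsilateral against contralateral (0.0130). Ribosomal proteins passed for ipsilateral against sham with library totals alone (0.0451) and without Hspa1a and Hspa1b (0.0465). Without ipsilateral replicate 5, hypoxia, oligodendrocyte precursor, glucocorticoid and cholesterol genes passed for ipsilateral against contralateral (adjusted p = 0.0415 for each), and without contralateral replicate 4 cholesterol (0.0182) and glucocorticoid genes (0.0486) did. Glutamate receptors passed there, lower, without ipsilateral replicate 4 (0.0274). Astrocyte markers passed without sham replicate 5 in ipsilateral cortex (0.0250), and in contralateral cortex against sham without sham replicate 2 (0.0174), sham replicate 5 (0.0215), contralateral replicate 1 (0.00791) or contralateral replicate 6 (0.0430). Microglia markers passed in the latter comparison without sham replicate 5 (0.0268) or contralateral replicate 1 (0.0175), and circadian genes, lower, without contralateral replicate 1 (0.0390). For ipsilateral against sham, translation factors passed without sham replicate 5 (0.0313), and ribosomal proteins without that library (0.0320), ipsilateral replicate 5 (0.0159) or any 1 contralateral library (0.0480, 0.0427, 0.0373 and 0.0460 without replicates 1, 4, 5 and 6).

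All tests of explanations in the following paragraphs were chosen after the results had been seen, on the same data, with their thresholds.

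Oligodendrocyte markers lay higher in ipsilateral cortex, by 0.64 ± 0.26 in score (SE) against contralateral and 0.73 ± 0.27 against sham. Microglia markers lay higher as well, by 0.44 ± 0.10 against contralateral and 0.69 ± 0.16 against sham. Oligodendrocyte precursor markers changed by 0.26 ± 0.14 and 0.25 ± 0.13 but did not pass (camera adjusted p = 0.163 and 0.189). Higher non-neuronal markers are what a lower share of neuronal material would bring. Such a share should raise astrocyte markers alike and lower neuron markers. Against contralateral cortex the astrocyte score changed by 0.0011 ± 0.08 and the neuron score by 0.07 ± 0.05. The oligodendrocyte score rose above the astrocyte score by 0.64 ± 0.26 (exact two-sided permutation p = 0.0571, 0.329 adjusted over 23 score tests). Against sham this difference was 0.62 ± 0.31 (exact two-sided permutation p = 0.171, 0.438 adjusted over 23 score tests). The astrocyte score thus showed no rise of that size, but neither difference passed, so a lower neuronal share stays open. The neuron score cannot decide it, because TMM scaling centres the bulk of genes, which may be largely neuronal. Striatum in the ipsilateral dissection would bring striatal markers. Their score against sham was lower, at -0.72 ± 0.41 (exact two-sided permutation p = 0.257, 0.493 adjusted over 23 score tests). That cannot decide it, because an effect of the occlusion surgery on these markers stays open. Against contralateral cortex a score of 0.0058 ± 0.46 leaves striatum open too. White matter and other deep tissue were not tested. More material from oligodendrocytes, whose genes sham cortex also contains (Ptgds averaged 905 CPM there), may be a candidate source: 91.7% of the 12 members (all but Enpp2) lay within 2 SE of a common log2 change of 0.70 against contralateral cortex, a loose test since single genes have a wide SE and members are correlated (0.506 estimated).

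Striatal markers differed between libraries within groups: scores were 0.12, 0.20 and -0.32 in sham replicates 1, 2 and 5, and the libraries of replicates 4 and 5 were among the lowest in the groups with an occlusion (-1.19, -0.94, -1.41 and -1.31). A test of whether libraries of the same number deviate together gave an exact one-sided p of 0.0909 over 3456 relabellings within groups, so the day cannot be told apart from chance with 11 libraries. An effect of the occlusion surgery also stays open, because with the replicate block the larger of the adjusted p against sham was 0.127 (ipsilateral, with 0.00098 to 0.493 over its alternatives). The dissection may therefore have reached the striatum to differing extents, but no test here decides it.

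The 20 genes with the largest dispersion around the group means, among those above the 25th percentile of CPM, differed widely between libraries. Rfx2 ran from 37.0 to 19056 CPM and Sycp1 from 0 to 1901 CPM, and the set held 3.96% of counts in ipsilateral replicate 6 against 0.0585% in contralateral replicate 5. Libraries with the same number tended to deviate together (exact one-sided p = 0.0266), but the p adjusted over the 2 scores tested this way, 0.0532, misses the threshold, so the day stays open. The group stays open as well (smallest exact two-sided p of the 3 comparisons 0.400), because genes chosen for their spread within groups cannot test it. Library total stays open, with a Spearman correlation of -0.491 (permutation p = 0.130; Pearson r = -0.316, p = 0.347, and -0.483 without the 2 libraries with the most extreme totals).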
